A study of Mus musculus with 3 samples.

How the data were processed

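Single cells of wild-type mouse oesophagus were measured at 3 stages, with 1 library for each of E13.5, E16.5 and P0. Per the labels, oesophagi of 12, 9 and 7 animals from 2 to 3 litters were pooled within a stage and dissociated on ice with a cold-active protease at 10 mg/ml for 7, 9 and 12 min, and libraries were made with a 5′ single-cell gene expression kit. The authors made raw UMI counts per gene and cell barcode with Cell Ranger 6.0.2 on the mm10 build, per the file headers and the labels. The deposited matrices hold counts of cell-called barcodes for 32285 genes, of which 78 have a symbol that another gene also has, and these were kept apart by their Ensembl ID. A second deposited copy of each matrix that was present held the same values and was not used.

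Cells with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs passed the filter, 6133, 10341 and 18665 at E13.5, E16.5 and P0. Doublets were scored in each library with Scrublet as run in scanpy. Its automatic threshold marked 0.0114% of barcodes at E13.5 and 0% at E16.5, below the 0.5% set as failure, so the highest scores were removed there instead at 0.8% per 1000 barcodes (618 and 2338 barcodes). At P0 the automatic threshold marked 1889 barcodes, 7.85%, where 0.8% per 1000 barcodes would have been 19.3%. Doublet removal thus differed between P0 and the other stages, and no alternative removed P0 doublets at that rate. This left 5786, 8996 and 17022 cells, of which 880, 2078 and 2882 had fewer than 3000 UMIs.

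Cells of the 3 libraries were clustered together: counts scaled to 10000 per cell and log-transformed, 2000 variable genes chosen over libraries, 30 principal components, 15 neighbours and Leiden clustering at resolution 1. The 20 genes of the cell cycle list, haemoglobins, mitochondrial and ribosomal genes, Xist, Tsix, Y-linked genes and Lgr5 took no part. Other cell cycle genes could take part, and some, such as Aspm and Kif11, are among the leading genes of cluster 29. The clusters with most E13.5 cells holding Epcam and holding Nkx6-1, a gene of foregut mesenchyme, were clustered once more (sub-clusters numbered from 1000 and from 2000), a step chosen after seeing the data. A cluster was named from 25 marker sets fixed before the data were examined, by at least 3 markers found in at least 10% of its cells at 1.5 times their level elsewhere, together with its 10 leading genes of at least 20 CPM. Names end in "-like" because they rest on markers alone. Clusters led by genes of another organ or of another class, shallow clusters without leading markers, and mixtures stayed unnamed, and the lists of genes of other organs and the decision on cluster 27, led by genes of several leukocyte types, were made after seeing the data. Sex was read per cell from Xist and from the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, which gave 3755 male and 466 female cells at E13.5, 2903 and 3479 at E16.5, and 4962 and 8110 at P0. Cells with both signals made up 2.16%, 7.05% and 6.72%, and cells with neither 24.9%, 22.0% and 16.5%.

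UMIs were summed over the cells of a class in each library and scaled to CPM. Shares of cells have exact 95% binomial (Clopper-Pearson) intervals, CPM exact Poisson intervals, and ratios of CPM exact conditional binomial intervals. They cover counting error only, since cells of 1 library are not replicates of a stage. Ratios against 0 UMIs were taken against a floor of 3 UMIs. The 6 classes compared were chosen before the data were seen, namely epithelial-like, fibroblast-like, smooth-muscle-like, skeletal-muscle-like, blood-endothelial-like and glia-like, with a minimum of 50 cells in both libraries. Other classes were not compared, whatever their number of cells. A gene counted as higher or lower at a ratio of at least 2 or at most 0.5 with an interval that excludes 1 and at least 20 CPM and 30 UMIs in the higher library. Genes with at least 20 CPM in a compared library counted as measured.

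For epithelial-like cells the text names, in each comparison of successive stages, the 10 genes with the largest and the 10 with the smallest ratio, and 5 and 5 for fibroblast-like, smooth-muscle-like and skeletal-muscle-like cells. These were taken among genes past the rule with at least 100 CPM in the higher library, at least 0.2 times the highest CPM of any other named class there, the same direction past 2-fold in cells of both sexes where each had at least 30 UMIs, and names other than provisional, mitochondrial, ribosomal, haemoglobin, Xist, Tsix or Y-linked ones. Members of the gene lists and marker sets are also named with their values, and Lgr4, Lgr5, Lgr6 and Rspo1 to Rspo4 always. The 19 lists cover basal keratinocytes, suprabasal and cornified differentiation, simple epithelium, the ciliated programme, Wnt, Notch, BMP and TGF-beta and Hedgehog signalling, the cell cycle, fetal growth and imprinting, smooth muscle contraction, myogenic regulators, the sarcomere, extracellular matrix, antimicrobial and barrier stress, dissociation stress, ribosomal proteins, mitochondrial genes and haemoglobins. Which of the list members and markers to print in the text was chosen after their values were seen. A list's value is the median log2 ratio of its measured members, with an interval from 200 Poisson redraws of the counts. Cells with a Lgr5 UMI were set against the other cells of their class within a library where at least 30 held one.

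The filters, the rule for higher and lower, the lists, the marker sets and the rule for named genes were fixed before the data were examined. The alternatives fixed then were a stricter filter (3000 UMIs, 1000 genes, 5% mitochondrial), doublets kept, each library clustered on its own, Leiden resolution 2, cells of 1 sex, median-of-ratios size factors, every cell weighted the same, other minimums and a ratio of 4, genes limited to those at 0.2 times other classes or above, cells thinned to 3000 UMIs, and at least 2 Lgr5 UMIs. Alternatives that add or leave out single clusters were chosen after seeing the data.

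The rule was tested on simulated data, with 200 genes per comparison set to a ratio of 1.5, 3 or 5 in Poisson counts at the depths of each class. It called 97.0% to 100% of genes at 3-fold and all at 5-fold, at most 5.97% at 1.5-fold and at most 4 unchanged genes per comparison, and the intervals held the true ratio for 94.8% to 96.2% of genes. The simulation has no variation between animals or libraries.

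Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.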

Results

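Oesophagi of wild-type mice were profiled by droplet-based RNA sequencing of single cells at 3 stages: the embryonic days E13.5 and E16.5 and the day of birth, P0. Tissue of 12 animals at E13.5, 9 at E16.5 and 7 at P0 was pooled within each stage, and each pool gave 1 library. The deposited libraries hold 8794, 17096 and 24063 cell barcodes, with totals of 100154863, 126098734 and 177020272 unique molecular identifiers (UMIs). After filtering, 5786, 8996 and 17022 cells were kept, with medians of 13050, 7632.5 and 6567 UMIs per cell. With 1 library per stage, no difference between stages has a replicate check, and no p-value or standard error is given. Levels are given as CPM, the UMIs of a gene scaled to all UMIs of a cell class in a library. All intervals are 95% intervals that cover counting error only. A gene is called higher or lower where its ratio of CPM is at least 2 or at most 0.5, the interval of the ratio excludes 1, and the higher library has at least 20 CPM and 30 UMIs. The series is about Lgr5, a receptor for R-spondins, as a marker of progenitors of oesophageal epithelium and muscle. The comparisons below ask which cells held Lgr5 at each stage, and how each cell class differed between stages.

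Epithelial-like cells made up 5.44% of kept cells at E13.5 (315 cells, interval 4.87% to 6.06%), 10.3% at E16.5 (929 cells, 9.71% to 11.0%) and 36.4% at P0 (6189 cells, 35.6% to 37.1%). Smooth-muscle-like cells made up 4.77%, 6.99% and 10.3% (276, 629 and 1759 cells). Skeletal-muscle-like cells, progenitors and myocytes together, made up 0.864%, 1.66% and 7.89% (50, 149 and 1343 cells). With each library clustered on its own the smooth-muscle-like share at E13.5 was 12.7%, with called doublets kept 9.47%, and at the finer cluster resolution the skeletal-muscle-like share at E13.5 was 0.449%. Under the stricter cell filter the smooth-muscle-like share was highest at E16.5 (8.09% against 7.48% at P0), and with each library clustered on its own at E13.5. Fibroblast-like cells were 3.47%, 23.0% and 17.1% of kept cells, and blood-endothelial-like cells 2.97%, 4.14% and 4.25%. Glia-like cells were 1.76%, 4.65% and 3.25%, and myeloid-like cells 3.53%, 4.37% and 1.498%. Erythroid-like cells went the other way, with 22.7% at E13.5, 2.00% at E16.5 and 0.311% at P0, but their sexed cells were 1.61% female at E13.5 (0.862% to 2.74%) and 58.5% at E16.5, so this is not read as a change of the oesophagus. The unnamed share was 52.5%, 35.05% and 13.7%, so shares of the named classes cannot be read as shares of the organ. With 1 library per group, a cluster mostly of 1 library may be that library, not a type. Complement and immune genes were among the leading genes of some named clusters: C3 in the mesothelial-like cluster 2, C1s1 in the fibroblast-like cluster 39 and Gimap4 in the blood-endothelial-like cluster 24. Protease time also differed between the stages (7, 9 and 12 min), which can set the shares.

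**Figure D1:**
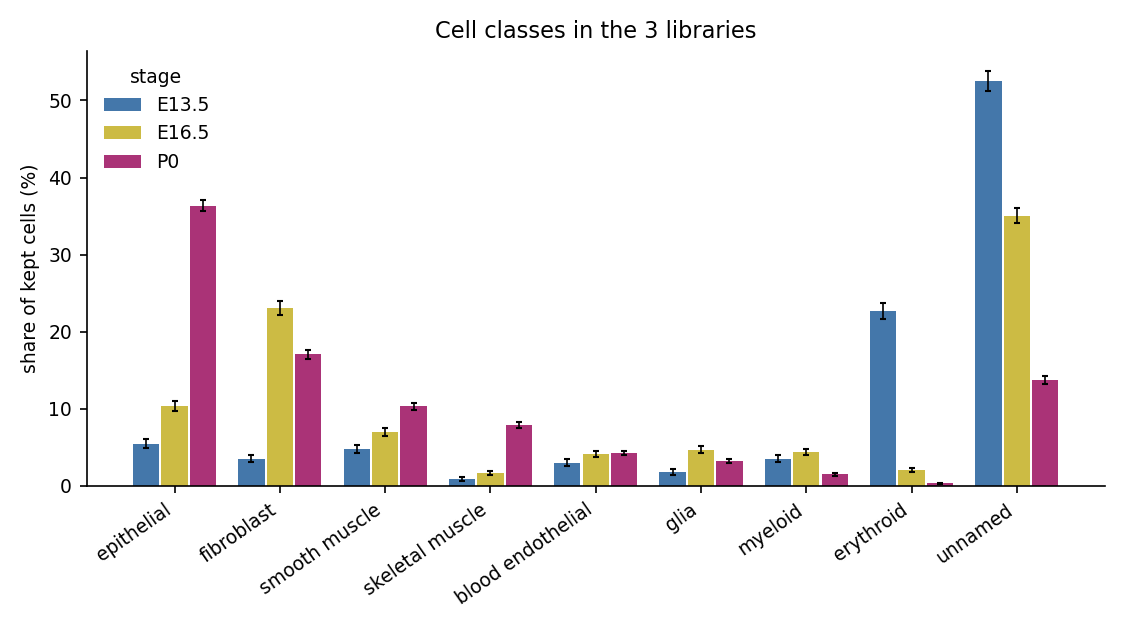
Share of kept cells (%, vertical axis) in each cell class (horizontal axis) at E13.5, E16.5 and P0, with bars starting at 0 and error bars for exact 95% binomial intervals. Epithelial-like cells are at 5.44%, 10.3% and 36.4%, and unnamed cells at 52.5%, 35.05% and 13.7%.

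Part of the E13.5 library was led by genes of other organs. Clusters led by genes of spleen or stomach mesenchyme such as Tlx1, Nkx2-5 and Barx1, of pancreas such as Cpa1, and of intestine such as Cdx2, with 3 cells of a limb cluster, held 2312 cells, 40.0% of that library. Among cells whose sex could be read, 2.55% of these came from female embryos (interval 1.89% to 3.36%), against 46.0% of smooth-muscle-like and fibroblast-like cells (41.1% to 50.9%). Of the epithelial-like cells at E13.5, 124 lay in 3 sub-clusters that were nearly all male (1.82% female), against 46.1% in the 191 others. The E13.5 skeletal-muscle-like cells were 4.76% female. At E16.5, a cluster of 1184 cells led by limb genes such as Msx1 and Hoxa11os was 1.71% female, and chondrogenic-like cells held 0 female cells of 104, which allows up to 3.48%. Epithelial-like cells were 65.4% female at E16.5 and 60.6% at P0.

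**Figure D2:**
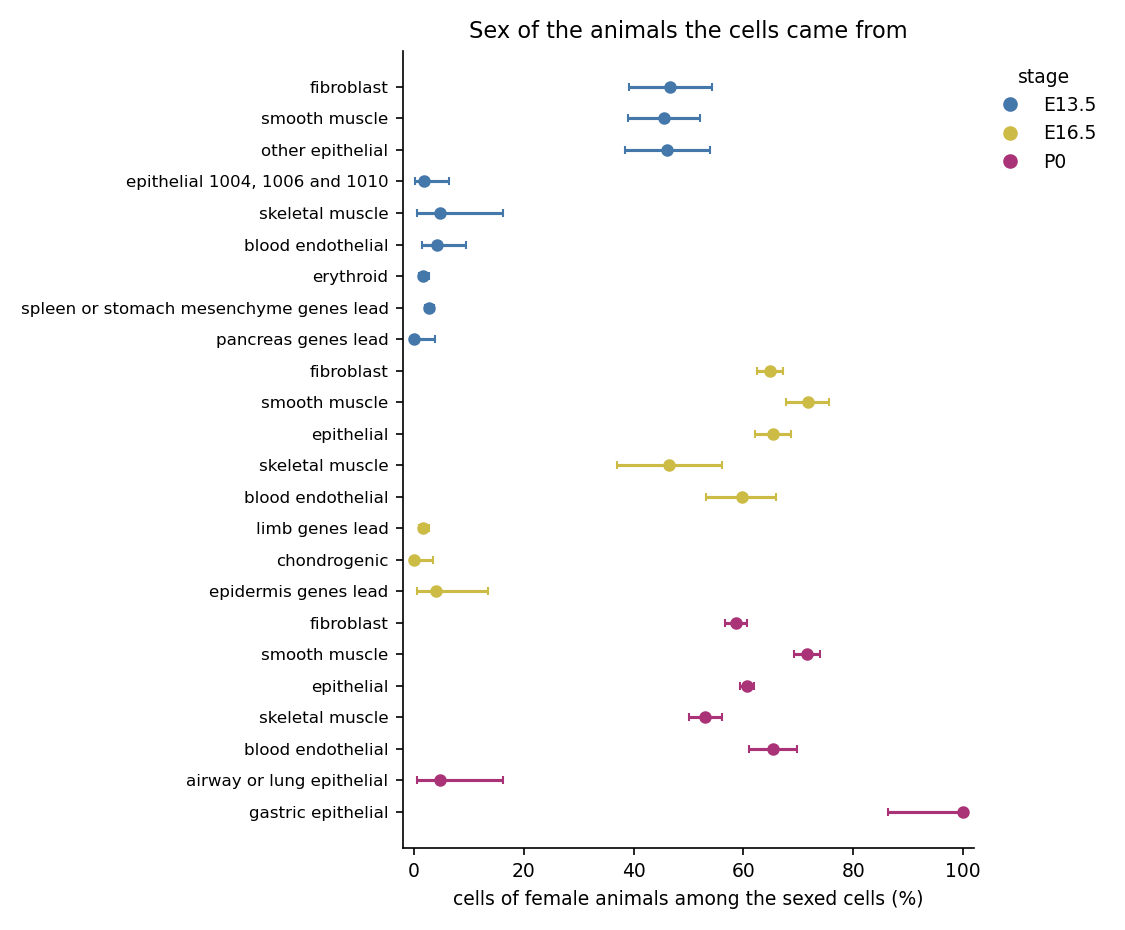
Cells of female animals among the sexed cells (%, horizontal axis) in cell groups of the E13.5, E16.5 and P0 libraries (vertical axis), with exact 95% binomial intervals. At E13.5, smooth-muscle-like, fibroblast-like and most epithelial-like cells lie near 46.0%, while clusters led by genes of other organs lie near 2.55%.

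Lgr5 (ENSMUSG00000020140) is a protein-coding gene on the minus strand of chromosome 10, from 115450311 to 115587780 in GRCm38 (mm10). In epithelial-like cells its level was 4.81 CPM at E13.5 (interval 3.05 to 7.22), 12.2 CPM at E16.5 (10.6 to 13.9) and 32.9 CPM at P0 (31.7 to 34.2). At P0 this was 2.70 times the E16.5 level (2.36 to 3.11). The E16.5 level was 2.53 times that at E13.5, but with less than 20 CPM at both stages it is not called higher, and the ratio was 1.30 with called doublets kept. Skeletal-muscle-like cells held 33.5 CPM at E13.5 (23.9 to 45.6), 93.2 CPM at E16.5 (82.2 to 105) and 22.3 CPM at P0 (19.4 to 25.5), so Lgr5 was higher at E16.5 than at either other stage. In cells thinned to 3000 UMIs the levels were 63.8 CPM (29.2 to 121), 74.1 CPM (49.2 to 107) and 16.9 CPM, with overlapping intervals at E13.5 and E16.5. Within that class, the progenitor cluster 20 held 62.0, 114 and 24.6 CPM. At the finer cluster resolution, 26 skeletal-muscle-like cells were left at E13.5, with 1.76 CPM. Fibroblast-like cells held 0.739, 8.59 and 15.6 CPM, most of it in cluster 8 (83.6 CPM at E16.5 and 90.2 CPM at P0), a cluster led by Postn and Eln. With each library clustered on its own, fibroblast-like cells at E13.5 numbered 1437 rather than 201 and held 29.004 CPM, which turns the direction from E13.5 to E16.5. Smooth-muscle-like cells stayed near the level of endothelial and myeloid cells, with 0.948, 0.460 and 2.37 CPM, the last being 11.4 CPM with called doublets kept. Glia-like cells held 4.09, 59.8 and 87.0 CPM, but their cluster 11 held 4.22, 1.82 and 3.27 CPM, and the difference lay in cluster 33, which had 3 cells at E13.5. At P0, neuron-like cells held 43.8 CPM, mesothelial-like cells 51.8 CPM and the 25 gastric-epithelial-like cells 179 CPM.

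Among epithelial-like cells, 3.81% (12 of 315), 11.4% (106 of 929) and 19.2% (1191 of 6189) held a Lgr5 UMI at E13.5, E16.5 and P0, at median depths of 13180, 16100 and 10929 UMIs. In blood-endothelial-like cells the shares were 1.16%, 0.538% and 0.829% at 10758, 4788 and 3251 UMIs, and in myeloid-like cells 0.490%, 0.509% and 0.784% at 13216, 3927 and 4674 UMIs. With every epithelial-like cell thinned to 3000 UMIs, which left out 20, 24 and 97 shallower cells, the shares were 1.36%, 3.76% and 9.70%. Skeletal-muscle-like cells held a Lgr5 UMI in 15 of 50 cells at E13.5, and in 38.3% and 9.75% of cells at E16.5 and P0, and in 10.6%, 14.3% and 4.35% after thinning. Of all cells with a Lgr5 UMI, 4.82% at E13.5, 25.7% at E16.5 and 69.2% at P0 were epithelial-like. Skeletal-muscle-like cells made up 6.02%, 13.8% and 7.62% of them, glia-like cells 2.01%, 16.46% and 5.64%, and unnamed cells 75.9%, 27.1% and 7.21%. Cluster 0, led by Tlx1 and Nkx2-5, held 120 of the 249 cells with a Lgr5 UMI at E13.5. Cluster 17, led by liver genes, held 28 there, and cluster 1, led by limb genes, held 77 of 413 at E16.5. Epithelial-like cells were 5.44%, 10.3% and 36.4% of kept cells, so these percentages also depend on the make-up of each library. Within the epithelium at P0, basal cluster 30 (led by Krt14, Col17a1 and Trp63) held 90.2 CPM and the cycling basal cluster 29 held 73.3 CPM, against 7.00 CPM in suprabasal cluster 18 and 1.56 CPM in cluster 28. At E16.5 the levels in clusters 30, 29 and 18 were 29.1, 64.4 and 1.98 CPM.

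**Figure D3:**
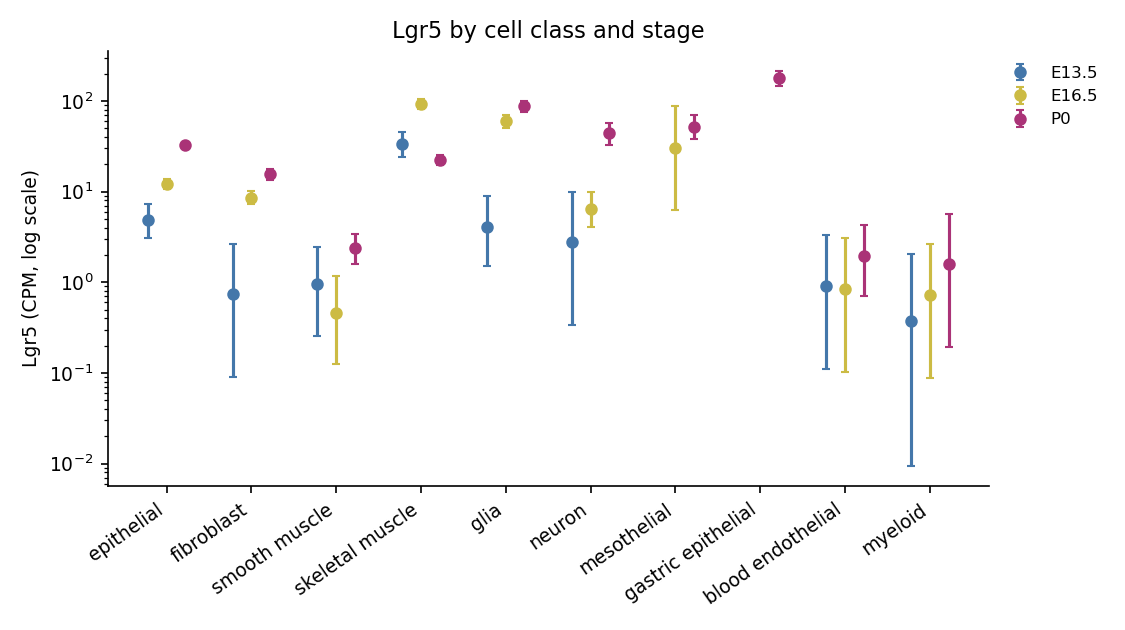
Lgr5 level (CPM, log scale, vertical axis) in each cell class (horizontal axis) at E13.5, E16.5 and P0, with exact 95% Poisson intervals. Epithelial-like cells are at 4.81, 12.2 and 32.9 CPM and skeletal-muscle-like cells at 33.5, 93.2 and 22.3 CPM, against at most 1.95 CPM in blood-endothelial-like and myeloid-like cells.

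Other genes of R-spondin signalling were read in other classes. Lgr4, the widely expressed relative of Lgr5, was at 116, 123 and 105 CPM in epithelial-like cells and at 41.8, 106 and 180 CPM in skeletal-muscle-like cells from E13.5 to P0. Lgr6 was highest in pericyte-like (22.6 CPM) and smooth-muscle-like cells (19.97 CPM) at P0, and was at 0.474 and 6.33 CPM in smooth-muscle-like cells before. Among the ligands, Rspo3 was highest in smooth-muscle-like cells, with 85.1, 154 and 164 CPM. Rspo1 was highest in mesothelial-like cells at P0 (236 CPM, 205 to 270), and Rspo2 in neuron-like cells (30.4, 69.1 and 118 CPM). In fibroblast-like cells Rspo2 was at 9.24, 21.4 and 5.72 CPM. Rspo4 stayed below 5 CPM in every named class.

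To describe the cells that held Lgr5, epithelial-like cells with a Lgr5 UMI were set against those without one in the same library. The groups lay in different clusters, with 94 of 106 Lgr5 cells and 312 of 823 others in basal clusters 29 and 30 at E16.5, and 1064 of 1191 and 2083 of 4998 at P0. The comparison within these clusters was not made, so the lists below do not separate Lgr5 cells from other basal cells. At E16.5 (106 against 823 cells), 20 of 21 measured suprabasal and cornified genes were lower, 0 higher and 1 neither (median log2 ratio -3.24), as in Krt13 (8501 and 903 CPM) and Krt4 (7293 and 937 CPM), the keratin pair of suprabasal oesophagus, in cells without and with Lgr5. At P0 (1191 against 4998 cells), 18 of 20 were lower (median -1.99), with Krt13 (12560 and 3188 CPM) and Krt4 (10862 and 2721 CPM). All 20 measured cell cycle genes were higher at E16.5 (median 2.56) and 16 of 17 at P0 (median 1.498), including the proliferation marker Mki67 (63.1 and 199.5 CPM) and the topoisomerase Top2a (65.8 and 206 CPM) at P0. Once cells were thinned to 3000 UMIs, which left 34 and 591 Lgr5 cells, 2 of 16 were higher at E16.5 (median 1.47) and 0 of 13 at P0 (median 0.80). Lgr5 was read anew in the thinned cells, so cells that lost their Lgr5 UMI joined the others (871 at E16.5 and 5501 at P0). This can weaken a difference at both stages, so smaller values after thinning are not read as an effect of depth alone. Of 11 basal keratinocyte genes, 5 were higher at E16.5 and 5 at P0 and none was lower (medians 0.98 and 0.76), among them the hemidesmosome gene Col17a1 (159.6 and 358 CPM) and the basal regulator Trp63 (207 and 455 CPM) at P0, but after thinning 1 of 11 was higher at E16.5 (median 0.86) and 0 of 11 at P0 (median 0.53). Hedgehog genes were higher in 4 of 5 at E16.5 and 2 of 3 at P0 (medians 1.69 and 1.48), as in the receptor Ptch1 (33.8 and 94.5 CPM) and the effector Gli3 (40.1 and 122 CPM), and after thinning in 0 of 5 (median 1.32) and 2 of 3 (median 1.02). Of the suprabasal genes, 15 of 19 and 18 of 19 were lower after thinning. The minimum of 30 UMIs is counted in the group with the higher level. With 34 Lgr5 cells of 3000 UMIs at E16.5, it bars weakly expressed genes from being called higher. For genes called lower it is counted in the 871 others. Higher calls lost at E16.5 are therefore not read as a loss of the difference. Wnt genes, a list that holds Lgr5 but here was read without it, had medians of 1.02 and 0.99, and of 0.46 and 0.62 after thinning, when 0 of 8 were higher at E16.5 and the list no longer stood out from random lists there (percentile 86.6). The simple epithelium genes had medians of -2.03 and -1.83. Cells with a Lgr5 UMI were the shallower ones, with medians of 14327.5 against 16541 UMIs at E16.5 and 9285 against 11633.5 UMIs at P0.

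In fibroblast-like cells at P0, the 73 cells with a Lgr5 UMI held more of the matrix genes Postn (670.3 and 3766 CPM) and Eln (1806 and 4269.6 CPM) than the 2833 without, with 46 and 364 of them in cluster 8, which these genes lead. At E16.5 (33 against 2039 cells) 12 of 16 cell cycle genes were lower (median -2.21), and Postn (145 and 1786 CPM) was higher. There too the groups lay in different clusters, with 21 of the 33 and 141 of the 2039 cells in cluster 8. In skeletal-muscle-like cells at E16.5 (57 against 92 cells), 15 of 17 sarcomere genes were lower in Lgr5 cells and 0 higher (median -3.48), and so was the differentiation factor Myog (437 and 85.7 CPM), while the satellite cell factor Pax7 (204 and 217 CPM) was not called. The progenitor cluster 20 held 52 of the 57 and 56 of the 92 cells, so the mix of progenitors and myocytes differed. Those cells were the deeper ones (25512 against 11540 UMIs). At P0 (131 against 1212 cells) the sarcomere median was 0.67, and it turned to -1.02 once cells were thinned to 3000 UMIs. With at least 2 Lgr5 UMIs (50 against 1212 cells) it was 1.54, with 13 of 19 genes higher and 0 lower. The direction at P0 thus depended on how the Lgr5 cells were taken. Smooth-muscle-like cells had fewer than 30 cells with a Lgr5 UMI at each stage and were not compared.

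From E13.5 to E16.5 the epithelial comparison asks how the epithelium differed as it became layered. Genes of the suprabasal layers were higher by large factors: Krt4 (9.84 and 6661 CPM) and Krt13 (17.8 and 7746 CPM), the keratin pair of suprabasal oesophagus, had ratios of 677 (509 to 922) and 435. Cell cycle genes were lower together, with Mki67 (254 and 84.2 CPM) and Top2a (442 and 89.9 CPM), and so were the Hedgehog ligand Shh (138 and 24.03 CPM) and the embryonic tight junction gene Cldn6 (101.9 and 3.66 CPM). In all, 1005 genes were higher and 1101 lower of 7937 measured (315 and 929 cells, 4778773 and 18558308 UMIs). Nearly all E13.5 cells sat in 7 sub-clusters of that stage, and nearly all E16.5 cells in clusters 18, 28, 29 and 30, so different clusters held the class at the 2 stages. Cells of male and female embryos gave the same direction past 2-fold for 1616 of 2080 genes with enough UMIs in both (77.7%).

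The 10 genes with the largest ratios at E16.5 by the fixed rule are given here. Psca, a surface antigen, had 0.209 and 1669.8 CPM with 1 UMI at E13.5 (ratio 7979.7, 1432 to 315191). With 0 UMIs at E13.5, the cornified envelope genes Cnfn (903 CPM) and Sprr3 (580.3 CPM) had ratios of 1439 and 924, and the protease inhibitor Csta1 (299 CPM) of 476. Each was taken against a floor of 3 UMIs and is not a lower bound. The protease inhibitor Spink5 (0.209 and 206 CPM), the membrane trafficking gene Mal (1.26 and 1072 CPM), the calmodulin-like Calml3 (1.05 and 726 CPM), the channel genes Lrrc26 (0.209 and 137 CPM) and Clic3 (0.209 and 132 CPM), and Krt4 completed the 10. The 10 with the smallest ratios were the adhesion genes Cadm2 (655 and 16.2 CPM) and Kirrel3 (290.5 and 15.7 CPM), the receptor tyrosine kinase Erbb4 (151 and 4.31 CPM), the replication histone Hist1h2ap (613 and 21.1 CPM), Cldn6, the growth factor midkine Mdk (1195 and 45.5 CPM), the heparan sulfate enzyme Hs6st3 (175 and 7.60 CPM), the BMP target Id3 (251 and 11.2 CPM), Bex1 (183 and 9.16 CPM) and the growth factor binding gene Igfbp4 (164 and 9.65 CPM). Without the 3 nearly all male sub-clusters of E13.5, the ratio of Erbb4 was 0.179 rather than 0.0285, and that of Krt4 401.

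Of 21 measured suprabasal and cornified differentiation genes, 19 were higher, 0 lower and 2 neither (median log2 ratio 7.00, 6.53 to 7.38), including the crosslinking enzyme Tgm3 (0 and 278 CPM), Krtdap (15.5 and 545 CPM) and Sprr1a (4.81 and 761 CPM). Krt10, a keratin of the epidermis, and the differentiation factor Klf4 passed in neither direction (32.9 and 39.6 CPM, and 137 and 159 CPM). Of 11 basal keratinocyte genes, 4 were higher, 1 lower and 6 neither (median 0.40, 0.30 to 0.50). The higher ones were the basal keratins Krt5 (112 and 709 CPM), Krt14 (9.63 and 111 CPM) and Krt15 (1569.7 and 6863 CPM) and the hemidesmosome gene Col17a1 (25.5 and 88.5 CPM), and the lower one was Sox2 (401 and 196 CPM), a factor of foregut identity, while Trp63 (315 and 275 CPM) was neither. Simple epithelium genes had 3 higher, 1 lower and 4 neither (median 0.58), with Krt7 (173 and 920.5 CPM), Krt19 (644 and 1581 CPM) and Cldn3 (78.7 and 165 CPM) higher and Cldn6 lower. All 20 cell cycle genes were lower (median -2.30, -2.37 to -2.19). The list of antimicrobial and barrier genes had 4 higher, 0 lower and 2 neither (median 3.02), among them the stress keratin Krt6a (14.4 and 1039 CPM), Anxa1 (638 and 3654 CPM), S100a14 (82.4 and 941 CPM) and the water channel Aqp3 (3.77 and 305 CPM). Without the nearly all male sub-clusters the basal median was 0.11 and the simple epithelium median 1.02.

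Signalling lists differed in direction. The BMP and TGF-beta list had 0 higher, 4 lower and 3 neither (median -1.35), with Bmp7 (68.6 and 20.4 CPM) and Tgfb2 (21.8 and 5.50 CPM) lower, and the Hedgehog list 0 higher, 2 lower and 2 neither (median -1.22), with Shh and Gli3 (116 and 33.8 CPM) lower and Ptch1 (159 and 101 CPM) neither. Of 9 Wnt genes, 2 were higher, 4 lower and 3 neither (median -0.51). The lower ones were the feedback genes Axin2 (22.4 and 2.69 CPM), Notum (49.0 and 0.269 CPM) and Rnf43 (186 and 73.8 CPM) and the target Sp5 (37.2 and 0 CPM), and the higher ones the ligands Wnt4 (192 and 608.2 CPM) and Wnt7b (3.77 and 24.5 CPM). This median turned to 0.11 without the nearly all male sub-clusters, 0.25 in cells of female embryos and 0.10 with every cell weighted the same. Without those sub-clusters the ratio of Axin2 was 0.342 rather than 0.120, and that of Notum 0.0927 rather than 0.00550. Notch genes had 2 higher, 0 lower and 5 neither (median 0.69), with the receptor Notch3 (70.3 and 135 CPM) and the target Hes1 (257 and 283 CPM) neither. The fetal growth and imprinted list had 1 higher, 4 lower and 7 neither (median -0.53), with H19 (1049 and 2365 CPM) higher and Hmga2 (262 and 43.4 CPM), Grb10 (446 and 81.6 CPM) and Igf2bp1 (119 and 39.1 CPM) lower. Dissociation stress genes had 4 higher, 0 lower and 3 neither (median 3.05), as in Fos (3.98 and 33.0 CPM) and Junb (12.1 and 121 CPM), and the median was 1.503 in cells of female embryos.

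Lists of other tissues were also read in these cells. Contractile genes had 2 higher of 3 (median 3.40), Mylk and Tpm2, which non-muscle cells also express. Extracellular matrix genes had 3 higher of 6 (median 0.66) and haemoglobin genes 4 higher and 1 lower of 5 (median 2.17). Ribosomal protein and mitochondrial genes had medians of -0.071 and -0.29, the former turning to 0.12 under median-of-ratios scaling. The ciliated and sarcomere lists had 0 measured members and the list of myogenic regulators 1. Scaled by median-of-ratios size factors instead of totals, 1240 genes were higher and 771 lower, so 61.7% rather than 47.7% of called genes were higher, a median shift of 0.19.

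**Figure D4:**
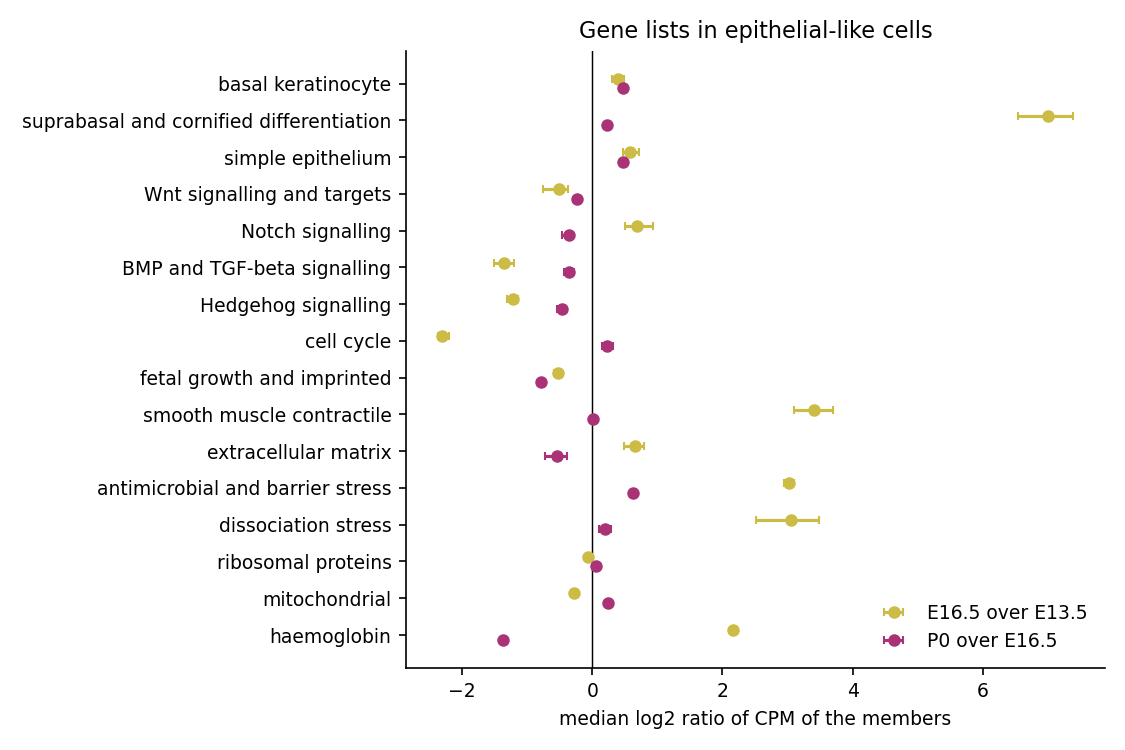
Median log2 ratio of CPM of the measured members of each fixed gene list (horizontal axis) in epithelial-like cells, for E16.5 over E13.5 and P0 over E16.5, with 95% intervals from redrawn counts. The suprabasal list lies at 7.00 and then 0.23, and the cell cycle list at -2.30 and then 0.23.

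From E16.5 to P0 the epithelial comparison asks what differed up to birth, once the epithelium was layered. Far fewer genes passed: 138 were higher and 196 lower of 7140 measured (929 and 6189 cells, with 83253927 UMIs at P0). The iron-binding antimicrobial protein Ltf (14.8 and 220.3 CPM) had the largest ratio, 14.9 (13.2 to 16.8), and Psca, already high, was at 1669.8 and 6931 CPM. Ltf is also among the leading genes of cluster 36, which has 554 cells at P0 alone and no class name. The filter on other named classes did not cover that cluster, so free RNA from it was not examined for Ltf. The basal keratin Krt14 (111 and 354 CPM) and Lgr5 (12.2 and 32.9 CPM) were higher, and the insulin-like growth factor gene Igf2 (578 and 249 CPM), the Notch target Hes1 (283 and 119 CPM) and the Hedgehog ligand Shh (24.03 and 7.07 CPM) were lower. Clusters 18, 28, 29 and 30 held 46.8%, 8.72%, 5.06% and 38.6% of epithelial-like cells at E16.5 and 28.6%, 20.5%, 7.25% and 43.6% at P0. The same direction past 2-fold was seen in cells of both sexes for 202 of 331 genes (61.0%).

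The other genes with the largest ratios by the rule were the NF-kappa-B inhibitor Nfkbia (36.1 and 179.9 CPM), Ecm1 (124 and 499 CPM), the transcription factor Creb5 (44.0 and 147 CPM), the serine protease Prss27 (46.9 and 148 CPM), the protease inhibitor Serpinb1a (68.7 and 217 CPM), the RNA-binding Cirbp (52.6 and 156 CPM) and the chaperone Clu (54.4 and 152 CPM). Those with the smallest ratios were Igfbp5 (226 and 52.5 CPM), the adhesion gene Nlgn1 (259.8 and 60.8 CPM), the uroplakins Upk3a (167 and 43.6 CPM) and Upk2 (251 and 108.3 CPM), Ndufa4l2 (239 and 64.1 CPM), the actin-binding Ppp1r9a (115 and 38.3 CPM), the lipid desaturase Scd2 (441 and 155 CPM), Krtdap (545 and 212.6 CPM), Lypd2 (569.5 and 232 CPM) and Hes1. In basal clusters 29 and 30 alone, the ratio of Psca was 83.5 rather than 4.15, that of Ltf 42.3, that of Ecm1 13.4, and that of Lypd2 turned to 1.07 from 0.408. Psca also went from 4.14 to 265 CPM in smooth-muscle-like and from 6.76 to 714 CPM in blood-endothelial-like cells, so its ratio in the basal clusters is not read as expression by basal cells. The ratio of Ltf there is not read so either, since free RNA from cluster 36 was not examined. Free RNA of Ecm1 and Lypd2 in the basal clusters was not examined, so the same holds for their ratios there.

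Of 11 basal keratinocyte genes, 3 were higher and 0 lower (median 0.48, 0.45 to 0.51): Krt14, the integrin Itga6 (41.4 and 84.8 CPM) and Col17a1 (88.5 and 191 CPM). Of 21 suprabasal genes, 0 were higher, 2 lower and 19 neither (median 0.23, 0.21 to 0.25). The lower ones were Krtdap and Sprr1b, which had 37.2 and 0.0120 CPM, while Krt13 (7746 and 11055 CPM), Cnfn (903 and 1057 CPM) and Sprr3 (580.3 and 366 CPM) passed in neither direction. In clusters 29 and 30 alone the suprabasal median was 0.92, with ratios of 13.3 for Cnfn and 3.99 for Krt13. Since the same list had medians of 2.34 to 3.76 in the classes outside the epithelium, these values are not read as expression by basal cells. Cell cycle genes had 0 higher, 0 lower and 10 neither (median 0.23), with Mki67 (84.2 and 85.1 CPM) and Top2a (89.9 and 88.3 CPM). The simple epithelium list had 7 of 7 neither (median 0.48), and the barrier list 2 higher and 5 neither (median 0.63), the stress keratins Krt6b (7.49 and 48.9 CPM) and Krt17 (180.2 and 489 CPM).

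Of 8 Wnt genes, 2 were higher (Lgr5 and Dkk3 (15.7 and 31.8 CPM)), 1 lower (Rnf43 (73.8 and 35.1 CPM)) and 5 neither (median -0.23). Hedgehog genes had 0 higher, 2 lower and 2 neither (median -0.47), Shh and Ptch1 (101 and 43.6 CPM) being the lower ones, and the median was 0.53 in cells of male embryos. Notch genes had 0 higher, 1 lower and 6 neither (median -0.35), and BMP and TGF-beta genes 3 of 3 neither (median -0.36). Fetal growth and imprinted genes had 0 higher, 3 lower and 8 neither (median -0.78, -0.80 to -0.77), with Igf2, Hmga2 (43.4 and 14.6 CPM) and Grb10 (81.6 and 33.0 CPM) lower. Dissociation stress genes had 1 higher and 8 neither (median 0.20). Extracellular matrix genes had 2 lower and 5 neither (median -0.54), and haemoglobin genes 4 of 4 lower (median -1.37). The contractile, ribosomal and mitochondrial medians were 0.018, 0.053 and 0.25, and the ciliated and sarcomere lists had 1 measured member each. Under median-of-ratios scaling 208 genes were higher and 105 lower, so 66.5% rather than 41.3% of called genes were higher, a median shift of 0.20. From E13.5 to P0, 1036 genes were higher and 1446 lower of 7922, with medians of 6.98 for the suprabasal and -2.14 for the cell cycle list, and under median-of-ratios scaling 1569 were higher and 647 lower (70.8% rather than 41.7% higher, a shift of 0.42).

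Fibroblast-like cells were compared to describe the stroma around the epithelium and muscle. From E13.5 to E16.5 they held more matrix and fewer cell cycle transcripts: Col1a1 (1298 and 7879.6 CPM), Postn (3.70 and 175 CPM) and elastin Eln (27.3 and 269.5 CPM) were higher, and Mki67 (423 and 197 CPM) and Top2a (706 and 236 CPM) lower. In all, 1219 genes were higher and 981 lower of 8040 (201 and 2072 cells), with the same direction past 2-fold in both sexes for 78.9% of those with enough UMIs. Nearly all E13.5 cells sat in sub-clusters 2006 to 2008, most E16.5 cells in cluster 9, and most P0 cells in clusters 34 and 39. The 5 largest ratios belonged to the monooxygenase Fmo2 (0 and 514 CPM, a ratio of 464 against a floor of 3 UMIs), the aggrecan-cleaving protease Adamts5 (0.739 and 168 CPM), the prostaglandin-degrading enzyme Hpgd (1.85 and 305 CPM), the microfibril gene Mfap5 (5.54 and 841 CPM) and Mageb18 (0.739 and 102.1 CPM). The 5 smallest were the replication histones Hist1h2ap (963 and 43.7 CPM), Hist1h2bj (115 and 9.78 CPM), Hist1h2ab (233 and 21.1 CPM) and Hist1h2ae (465 and 53.7 CPM) and the lactate dehydrogenase subunit Ldhb (166 and 19.8 CPM). Matrix genes had 17 higher, 0 lower and 4 neither (median 2.55), cell cycle genes 19 lower of 20 (median -1.91), and contractile genes 9 higher of 12 (median 1.83), such as Acta2 (334 and 682 CPM). Wnt genes had 6 higher, 0 lower and 4 neither (median 1.08), with the feedback gene Nkd1 (9.24 and 52.0 CPM) and the antagonist Dkk2 (2.96 and 25.4 CPM), and the median was 0.23 at the finer cluster resolution. With each library clustered on its own, the ratio of Adamts5 was 5.67, that of Hpgd 18.2, that of Postn 2.64 and that of Mki67 0.880, and the cell cycle median -1.04. Median-of-ratios scaling gave 1056 higher and 1236 lower (46.1% rather than 55.4% higher, a shift of -0.11).

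From E16.5 to P0, 514 genes were higher and 461 lower in fibroblast-like cells of 7963 (2072 and 2906 cells), 81.1% of them in the same direction in both sexes. Elastin Eln (269.5 and 1879.8 CPM), Postn (175 and 764 CPM) and Tnc (18.5 and 331 CPM) were higher, Col1a1 (7879.6 and 4198 CPM) was not called, and the Hedgehog target Ptch1 (486 and 126 CPM) was lower. By the rule, Cilp (1.14 and 169 CPM), the neuropeptide receptor subunit Ramp1 (4.10 and 101.8 CPM), the immediate early gene Egr1 (5.92 and 138 CPM), Tnc and Hmcn2 (7.74 and 137 CPM) had the largest ratios. The BMP and Wnt antagonist Sostdc1 (133 and 11.4 CPM), the glutamate receptor Grm8 (256 and 24.3 CPM), Lrmda (509.7 and 58.2 CPM), the adhesion gene Tenm2 (397 and 51.8 CPM) and Zfp536 (439 and 59.5 CPM) had the smallest. Matrix genes had 7 higher, 1 lower and 14 neither (median 0.55), and cell cycle genes 12 lower and 3 neither (median -1.80), as in Mki67 (197 and 57.2 CPM). Hedgehog genes had 3 lower and 4 neither (median -0.27), with Gli1 (45.8 and 20.9 CPM), and Wnt genes 4 higher, 4 lower and 4 neither (median -0.38). BMP and TGF-beta genes had 5 higher, 1 lower (Bmp4 (107 and 39.3 CPM)) and 2 neither (median 1.41), a median that turned to -0.33 with each library clustered on its own. Contractile genes had 0 higher, 7 lower and 5 neither (median -1.05), with Acta2 (682 and 237 CPM), and turned to 0.34 with called doublets kept. Dissociation stress genes, Egr1 among them, had 5 higher and 1 neither (median 1.88). Transcripts of the epithelium were also read in fibroblast-like cells at P0, with Krt4 at 529 CPM, 5.54% of the epithelial level, against 350 CPM in smooth-muscle-like and 560 CPM in blood-endothelial-like cells.

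Smooth-muscle-like cells were compared because the series concerns the muscle as well as the epithelium. From E13.5 to E16.5 the myosin heavy chain Myh11 (3831 and 8866 CPM) and desmin Des (277 and 1893 CPM) were higher, while Acta2 (10442 and 8667 CPM) and Actg2 (4208 and 5552 CPM), actins of smooth muscle, passed in neither direction. In all, 732 genes were higher and 483 lower of 7441 (276 and 629 cells, in sub-clusters 2000 and 2003 to 2005 at E13.5 and mainly cluster 14 later), and 78.1% of those with enough UMIs went the same way past 2-fold in both sexes. By the rule, the largest ratios were those of muscle creatine kinase Ckm (0.948 and 206 CPM), fast troponin Tnnt3 (1.42 and 118 CPM), the small heat shock gene Cryab (3.08 and 177 CPM), Rgs6 (4.50 and 254 CPM) and the intermediate filament gene Synm (7.59 and 323 CPM). The smallest were those of Crmp1 (103 and 1.496 CPM), the fetal chromatin gene Hmga2 (261 and 7.48 CPM), Bst2 (168 and 12.9 CPM), Frmpd4 (117 and 9.89 CPM) and Hist1h2ap (365 and 32.2 CPM). Contractile genes had 5 higher, 0 lower and 7 neither (median 0.75, 0.71 to 0.78), and sarcomere genes 5 higher, 2 lower and 2 neither (median 1.46), with Acta1 (19.2 and 93.1 CPM) higher. Cell cycle genes had 0 higher, 9 lower and 11 neither (median -0.97), with Mki67 (203 and 179 CPM) neither, and Hedgehog genes 3 lower and 4 neither (median -0.86), with Gli1 (39.1 and 13.001 CPM). Wnt genes had 3 higher, 1 lower and 5 neither (median 0.81). With the unnamed E13.5 cluster 4 added to the class, the contractile median was 2.13, the sarcomere median 3.83, the Wnt median 0.037 and the ratio of Acta2 turned to 1.93. Cluster 4 (1112 cells at E13.5) was led by genes of spleen or stomach mesenchyme, and its markers were those of fibroblasts. Its sexed cells were 972 male and 19 female. These values are therefore not read as those of oesophageal smooth muscle.

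From E16.5 to P0, 175 genes were higher and 282 lower in smooth-muscle-like cells of 7153 (629 and 1759 cells). Limited to genes at 0.2 times other classes or above, 81 were higher and 201 lower. Of the called genes with enough UMIs, 65.6% went the same way past 2-fold in both sexes. All 12 contractile genes were neither (median 0.21), with Myh11 (8866 and 9458 CPM) and Acta2 (8667 and 11073 CPM), while Tnnt3 (118 and 474 CPM) was higher and Acta1 (93.1 and 31.2 CPM) lower. The rule named the thioredoxin inhibitor Txnip (102.2 and 574 CPM), S100a10 (62.7 and 339 CPM), the interferon-induced Ifitm3 (43.6 and 228 CPM), Atcayos (21.7 and 106 CPM) and Anxa11 (25.9 and 112 CPM) as highest in ratio. It named carbonic anhydrase Car3 (423 and 54.3 CPM), the netrin receptor Dcc (146 and 22.7 CPM), Tafa1 (342 and 65.3 CPM), Prr16 (139 and 36.6 CPM) and Stac (194 and 53.8 CPM) as lowest. Sarcomere genes had 2 higher, 3 lower and 4 neither (median -0.023, or 0.10 under median-of-ratios scaling), cell cycle genes 7 lower and 8 neither (median -0.81), and fetal growth and imprinted genes 3 lower and 9 neither (median -0.57). Wnt genes had 1 higher and 9 neither (median 0.22), and Hedgehog genes 1 lower and 4 neither (median -0.63). The contractile median was 0.12 with called doublets kept. Under median-of-ratios scaling 244 genes were higher and 193 lower, so 55.8% rather than 38.3% of called genes were higher, a shift of 0.12.

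Skeletal-muscle-like cells were compared for the striated part of the muscle, with 50 cells at E13.5. From E13.5 to E16.5 the differentiation factors Myog (1166 and 241 CPM) and Myod1 (290.2 and 99.3 CPM) were lower, and the progenitor factors Pax7 (79.5 and 211 CPM) and Myf5 (21.7 and 71.4 CPM) were higher. Pax3, a factor of somite-derived muscle, was at 47.7 and 0 CPM, and Isl1 and Tbx1, factors of head and pharyngeal muscle, were at 6.69 and 219.6 CPM (ratio 32.8, 16.55 to 76.3) and 22.6 and 68.9 CPM. In all, 1655 genes were higher and 192 lower of 7219, and under median-of-ratios scaling 900 were higher and 714 lower (55.8% rather than 89.6% higher, a shift of -0.36). Both sexes gave the same direction past 2-fold for 515 of 1419 genes (36.3%), with 2 female cells at E13.5. The myocyte cluster 22 held 25 of 50 cells at E13.5 and 41 of 149 at E16.5, the progenitor cluster 20 the others. By the rule, Ebf1 (0.836 and 769.8 CPM), Thsd7b (1.67 and 279.9 CPM), the sodium leak channel Nalcn (2.51 and 404 CPM), Pcolce2 (3.35 and 113 CPM) and Isl1 had the largest ratios, and the sarcomere genes Tnnc1 (138 and 11.1 CPM), Myh3 (144 and 14.996 CPM) and Myl4 (161 and 23.6 CPM) and the regulators Vgll2 (196 and 27.8 CPM) and Meis2 (229 and 34.3 CPM) the smallest. Sarcomere genes had 0 higher, 11 lower and 6 neither (median -1.25), with Actc1 (2015 and 888 CPM) lower, and the median was -0.028 with every cell weighted the same. Myogenic regulators had 5 higher, 4 lower and 5 neither (median -0.30). All 7 Wnt genes were higher (median 1.63), Lgr5 (33.5 and 93.2 CPM), Lgr4 (41.8 and 106 CPM), Axin2 (3.35 and 23.2 CPM) and Lef1 (26.8 and 82.8 CPM) among them. Notch, Hedgehog and matrix genes were higher in 4 of 6, 3 of 4 and 12 of 16, and cell cycle genes in 3 of 20 (median 0.20, which turned to -0.16 under median-of-ratios scaling), with 0 lower in each.

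From E16.5 to P0, 446 genes were higher and 391 lower in skeletal-muscle-like cells of 7754 (149 and 1343 cells), with the same direction in both sexes for 517 of 834 (62.0%). Cell cycle genes had 0 higher, 15 lower and 5 neither (median -1.26), with Top2a (594 and 251 CPM) lower and Mki67 (474 and 275 CPM) neither. Lgr5 (93.2 and 22.3 CPM), Lef1 (82.8 and 28.04 CPM) and Axin2 (23.2 and 9.28 CPM) were lower, while Lgr4 (106 and 179.9 CPM) passed in neither direction, so the Wnt list had 1 higher, 3 lower and 4 neither (median -0.041). All 13 myogenic regulators were neither (median -0.036), among them Pax7 (211 and 293 CPM), Myog (241 and 228 CPM) and Isl1 (219.6 and 192 CPM). The oestrogen receptor Esr1 (11.1 and 160 CPM), the elastic fibre gene Fbln5 (16.8 and 137 CPM), Txnip (25.3 and 189 CPM), Calcr (36.4 and 233 CPM), a receptor of quiescent satellite cells, and Itih5 (64.6 and 362 CPM) had the largest ratios by the rule. The smallest were those of the replication genes Hist1h2an (120.3 and 15.1 CPM), Hist2h2ac (227 and 55.0 CPM), Hist1h4c (119 and 30.1 CPM) and Rrm2 (103 and 27.5 CPM) and the integrin Itga4 (149.96 and 29.4 CPM). Sarcomere genes had 10 higher, 0 lower and 8 neither (median 1.26), with Myh3 (14.996 and 96.9 CPM). That median turned to -0.61 in progenitor cluster 20 alone and to -1.05 with every cell weighted the same, and the ratio of Myh3 turned to 0.728 from 6.46 in cluster 20.

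Blood-endothelial-like and glia-like cells were compared as classes outside epithelium and muscle. In blood-endothelial-like cells (172, 372 and 724 cells) 4.13% of sexed cells were female at E13.5 (1.36% to 9.38%) and 59.7% at E16.5, a limit on that comparison. None of the 20 cell cycle genes passed from E13.5 to E16.5 (median -0.28), and all 20 were lower from E16.5 to P0 (median -2.10), as in Mki67 (326 and 82.9 CPM) and Top2a (358 and 63.4 CPM). Matrix genes were higher in 8 of 11 and then in 7 of 19, with Eln (24.1 and 513 CPM) and Fbn1 (79.8 and 461 CPM) in the later step, whose median of 0.90 turned to -0.31 with every cell weighted the same. Glia-like cells were 27.4% female at E13.5 (18.7% to 37.5%) and 63.7% at E16.5, which limits that comparison too. In them 12 of 20 cell cycle genes were lower by E16.5 (median -1.17) and 10 of 16 by P0 (median -1.07). Matrix genes were higher in 13 of 16 by E16.5 (median 2.11), with Col1a2 (66.9 and 1717 CPM) and Col3a1 (107 and 1657 CPM), and so were Lgr4 (55.3 and 119 CPM) and the Notch target Hey2 (21.2 and 139 CPM). The glia-like cluster 33 had 3 cells at E13.5 and 137 at E16.5, and free RNA of fibroblast-like cells was not examined in either class. The matrix difference is therefore not read as a change within glia. From E13.5 to E16.5, 740 genes were higher and 400 lower of 7597 in blood-endothelial-like cells, and 1148 higher and 835 lower of 8145 in glia-like cells. Median-of-ratios scaling gave 451 higher and 806 lower (35.9% rather than 64.9% higher, a shift of -0.19), and 937 higher and 1136 lower (45.2% rather than 57.9%, a shift of -0.14). From E16.5 to P0 the counts were 597 and 436 of 7916, and 453 and 407 of 8112. Limited to genes at 0.2 times other classes or above, they were 310 higher and 406 lower in blood-endothelial-like cells, and 275 and 335 in glia-like cells. Both sexes gave the same direction past 2-fold from E13.5 to E16.5 for 216 of 803 genes (26.9%) in blood-endothelial-like cells, with 5 female cells at E13.5, and for 1085 of 1628 (66.6%) in glia-like cells. From E16.5 to P0 they did so for 517 of 763 (67.8%) and 359 of 601 (59.7%). Glia-like cells lay in cluster 11 at E13.5 and in clusters 11 and 33 later.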

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

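All tests of explanations in this part were chosen after the results they measure were seen. Lgr5 went in opposite directions in the epithelium and the skeletal muscle between E16.5 and P0. In epithelial-like cells the P0 level was 2.70 times the E16.5 level (interval 2.36 to 3.11), and in skeletal-muscle-like cells 0.239 times (0.199 to 0.288). The difference between the classes was not tested, since each stage has 1 library.

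For the higher Lgr5 level in the epithelium at P0, different shares of the basal and suprabasal clusters were argued against as the whole cause. The mix of cells inside a cluster was not examined. Within basal cluster 30 alone the ratio of Lgr5 was 3.10 (2.61 to 3.69). Within the cycling basal cluster 29 it was 1.14 with an interval of 0.868 to 1.52, so a higher level was not shown in every basal cluster, and a part played by the mix stays open. Free RNA was argued against as well, because the larger increase in blood-endothelial-like and myeloid-like cells was 1.11 CPM, with an upper bound of 5.72 CPM at P0, against 20.7 CPM in epithelial-like cells. A difference between the libraries other than age cannot be told apart from age with 1 library per stage. The ratio was 3.87 (2.95 to 5.16) in cells of male and 2.49 (2.08 to 3.01) in cells of female animals. An effect of age stays open as a biological explanation that was not tested.

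Some clusters without a class name and with at least 50 cells held Lgr5 with a lower bound above the highest upper bound of the blood-endothelial-like and myeloid-like cells of their library (3.29, 3.05 and 5.72 CPM at E13.5, E16.5 and P0). At E13.5 these were cluster 0, led by Wt1, Tlx1 and Nkx2-5, with 48.4 CPM in 1070 cells, cluster 17 with 41.4 CPM in 55 cells, and the mixed leukocyte cluster 27 with 9.62 CPM, all of it in 1 of 63 cells. Cluster 17 was led by the liver genes Afp, Alb and Apoa2, held 0 female cells of 46 sexed ones, which allows up to 7.71%, and was not counted among the clusters of other organs. Clusters of 30, 45 and 29 cells at E13.5, below the minimum of 50, had 11.8, 9.41 and 9.36 CPM. At E16.5 they were cluster 1, led by limb genes, with 29.5 CPM in 1184 cells, the shallow clusters 12 with 17.3 CPM and 13 with 26.5 CPM, and cluster 41, led by the epidermal keratins Krt1 and Krt10, with 11.8 CPM in 78 cells. At P0 they were cluster 12 with 53.3 CPM in 186 cells, cluster 13 with 97.0 CPM in 515 cells, and cluster 27 with 13.54 CPM in 217 cells. Clusters 12 and 13 had medians of 2320.5 and 1436 UMIs per cell at P0.

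The clusters of the E13.5 library led by genes of spleen or stomach mesenchyme, pancreas and intestine may be tissue of other organs carried along from few animals. Of their sexed cells 2.55% were female (1.89% to 3.36%), against 46.0% of smooth-muscle-like and fibroblast-like cells of the same library, as this explanation needs. A low female share was not limited to these clusters, with 1.61% in erythroid-like, 4.13% in blood-endothelial-like, 11.1% in neuron-like and 12.3% in myeloid-like cells of that library. Whether the cells of those classes came from the same animals or organs was not tested. A low share alone therefore does not show which cells are of other organs. Female cells without a sex call cannot fill this gap of 43.5 points, because 15.2% of the clusters' cells (13.8% to 16.8%) had neither signal. With every such cell counted as female, the female share would be 17.6% (16.1% to 19.3%), below the lower bound of 41.1% in smooth-muscle-like and fibroblast-like cells. No biological explanation was tested for these clusters.

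The skeletal-muscle-like cells of the E13.5 library read Pax3 and little Isl1, with 84.3 and 3.18 CPM in cluster 20, where E16.5 cells read 0 and 242 CPM. They may be muscle of another site carried along from few animals: 4.76% of the sexed cells were female (0.582% to 16.2%), below the lower bound of 41.1% in smooth-muscle-like and fibroblast-like cells. An earlier stage of the same muscle cannot be told apart, since 2 female cells against 40 male ones are too few to read Pax3 in female embryos. The comparison of skeletal-muscle-like cells between E13.5 and E16.5 carries this limit.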

How the results depend on the processing

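Changes with the alternatives are given here for shares, Lgr5 levels, counts of genes and list medians, and the cause was not tested for any of them. Alternatives that add or leave out single clusters were chosen after seeing the data. No paired analysis was possible because each stage has 1 library, and no library could be left out for the same reason. Without a test, a share, level, median or ratio counts as moved when it left its 95% interval, and a count of genes when it left a range of 1.5 times. A median or ratio counts as reversed only if its first value was called, by the rule for a gene or, for a list, by its percentile among random lists with an interval on 1 side of 0, and then changed its sign or direction. Changes of sign in values that had not been called are counted as higher or lower, or within the interval.

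Of 41 shares under alternatives, 15 stayed within their interval. Under the stricter filter the epithelial-like share was 6.23%, 13.6% and 45.1% at E13.5, E16.5 and P0, the smooth-muscle-like share 5.74%, 8.09% and 7.48%, and the skeletal-muscle-like share at P0 9.10%. With called doublets kept, the epithelial-like share was 9.56% at E16.5 and 33.4% at P0, the smooth-muscle-like share 9.47%, 8.86% and 12.1%, and the skeletal-muscle-like share at P0 8.68%. With each library clustered on its own, the epithelial-like share was 6.38%, 9.64% and 35.3%, and the smooth-muscle-like share 12.7%, 9.22% and 11.8%. At Leiden resolution 2 the smooth-muscle-like share was 6.90%, 9.88% and 11.2%, and the skeletal-muscle-like share at E13.5 0.449%. Without the 3 nearly all male sub-clusters the epithelial-like share at E13.5 was 3.30%, with cluster 36 it was 39.6% at P0, and with cluster 4 the smooth-muscle-like share at E13.5 was 23.99%. The epithelial-like share stayed highest at P0 under the alternatives run at all 3 stages. The smooth-muscle-like share was highest at E13.5 with cluster 4 and with each library clustered on its own, and at E16.5 under the stricter filter. Cluster 4 was led by genes of spleen or stomach mesenchyme, so the share with it is not read as oesophageal smooth muscle.

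Of 93 Lgr5 levels, 60 stayed within their interval, 20 were higher and 13 lower. Under the stricter filter the smooth-muscle-like level at P0 was 3.77 CPM. With called doublets kept it was 9.19 CPM in epithelial-like cells at E13.5, 1.72 and 11.4 CPM in smooth-muscle-like cells at E16.5 and P0, and 82.0 CPM in skeletal-muscle-like cells at E16.5. With each library clustered on its own it was 34.3 CPM in epithelial-like cells at P0, 29.004 and 13.7 CPM in fibroblast-like cells at E13.5 and E16.5, and 6.78 CPM in smooth-muscle-like cells at P0. At Leiden resolution 2 it was 1.76 CPM in skeletal-muscle-like cells at E13.5. In male cells it was 9.95 and 38.5 CPM in epithelial-like cells at E16.5 and P0, 19.6 CPM in fibroblast-like cells at P0, 0 (which allows up to 1.61 CPM) and 5.98 CPM in smooth-muscle-like cells at E16.5 and P0, and 113 CPM in skeletal-muscle-like cells at E16.5. In female cells it was 29.8 CPM in epithelial-like cells at P0, 10.3 and 10.7 CPM in fibroblast-like cells at E16.5 and P0, 1.03 CPM in smooth-muscle-like cells at P0, and 76.6 CPM in skeletal-muscle-like cells at E16.5. Thinned to 3000 UMIs it was 15.5 and 47.5 CPM in epithelial-like cells at E16.5 and P0, 0 in fibroblast-like and in smooth-muscle-like cells at E13.5 (upper bounds of 6.27 and 4.71 CPM), and 63.8, 74.1 and 16.9 CPM in skeletal-muscle-like cells at the 3 stages. With cluster 36 it was 30.7 CPM in epithelial-like cells at P0, in clusters 29 and 30 alone 34.7 and 86.7 CPM at E16.5 and P0, and in cluster 20 alone 62.0 and 114 CPM at E13.5 and E16.5. Under every alternative run at both stages, the level was higher at P0 than at E16.5 in epithelial-like cells and lower in skeletal-muscle-like cells. All 12 shares of cells with a Lgr5 UMI were lower after thinning.

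Of 160 counts of genes, 118 stayed within 1.5 times, among them all 13 with median-of-ratios size factors and all 13 with doublets kept. The others follow from the rule itself, apart from 3. In the order E16.5 over E13.5, P0 over E16.5 and, for epithelial-like cells, P0 over E13.5, the counts without a minimum of CPM or UMIs were 4849, 2726 and 6211 in epithelial-like, 4215 and 3758 in fibroblast-like, 2953 and 2269 in smooth-muscle-like, 2955 and 2404 in skeletal-muscle-like, 2280 and 2327 in blood-endothelial-like and 3202 and 1956 in glia-like cells. With at least 100 CPM they were 683, 73 and 781 in epithelial-like, 856 and 300 in fibroblast-like, 409 and 122 in smooth-muscle-like, 467 and 226 in skeletal-muscle-like, 384 and 219 in blood-endothelial-like and 776 and 223 in glia-like cells. At a ratio of at least 4 they were 740, 62 and 890 in epithelial-like, 522 and 265 in fibroblast-like, 289 and 97 in smooth-muscle-like, 410 and 154 in skeletal-muscle-like, 188 and 256 in blood-endothelial-like and 439 and 191 in glia-like cells. Limited to genes at 0.2 times other classes or above, P0 over E16.5 gave 217 in epithelial-like cells (97 higher and 120 lower) and 282 in smooth-muscle-like cells (81 higher and 201 lower). With every cell weighted the same, E16.5 over E13.5 gave 1724 in blood-endothelial-like cells.

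Of 1519 list medians, 848 stayed within their interval, 308 were higher, 354 lower and 9 reversed. The reversed ones were all in P0 over E16.5. With every cell weighted the same, the skeletal-muscle-like sarcomere median was -1.05 and contractile median -0.53, and the blood-endothelial-like matrix median -0.31. In cluster 20 alone the sarcomere median was -0.61, and in clusters 29 and 30 alone the epithelial-like cell cycle median -0.024. With each library clustered on its own the fibroblast-like BMP and TGF-beta median was -0.33. With called doublets kept the fibroblast-like contractile median was 0.34 and the blood-endothelial-like ribosomal median 0.029, and in female cells the latter was 0.017.

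Of 2034 ratios of named genes, 1209 stayed within their interval, 458 were higher, 365 lower and 2 reversed: Lypd2 at 1.07 in epithelial-like clusters 29 and 30 alone, and Myh3 at 0.728 in skeletal-muscle-like cluster 20 alone, both in P0 over E16.5. Of 148 list medians of Lgr5 cells against the rest, 72 stayed within their interval, 29 were higher, 43 lower and 4 reversed, all at P0 after thinning: -0.68 for haemoglobin in fibroblast-like cells, and -1.02 for the sarcomere, -0.013 for mitochondrial genes and 0.75 for haemoglobin in skeletal-muscle-like cells. In epithelial-like cells at E16.5, thinning took 4 medians that had not been called across 0: haemoglobin from 0.57 to -4.22, BMP and TGF-beta from -0.051 to 1.01, ribosomal proteins from 0.086 to -0.14 and mitochondrial genes from -0.029 to 0.047. Thinning also left fewer calls of single genes in epithelial-like cells. In cell cycle genes 2 of 16 were still higher at E16.5 and 0 of 13 at P0. In basal keratinocyte genes it was 1 of 11 and 0 of 11, and in Hedgehog genes 0 of 5 and, as before, 2 of 3. At E16.5 the minimum of 30 UMIs in 34 thinned cells bars weakly expressed genes from being called higher. Calls lost at that stage are therefore not read as a loss of the difference. Cells that lost their Lgr5 UMI by thinning joined the others at both stages, which can weaken a difference as well. The medians stayed above 0 with 34 and 591 Lgr5 cells left, at 1.47, 0.86 and 1.32 for the 3 lists at E16.5 and 0.80, 0.53 and 1.02 at P0. The Wnt median of these cells at E16.5 fell to 0.46, at percentile 86.6, and was no longer called.

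Some alternatives left fewer than 50 cells in a class and gave no value. For E16.5 over E13.5 these were the stricter filter (45 cells at E13.5), Leiden resolution 2 (26), male cells (40), female cells (2) and cluster 20 alone (25) in skeletal-muscle-like cells, and female cells in blood-endothelial-like (5) and glia-like cells (26). Clusters 29 and 30 held 0 epithelial-like cells at E13.5, so comparisons with that stage were not run on them. Depth limits the Lgr5 shares and the genes near the minimum of 30 UMIs.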

Other observations

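The clusters and genes below were chosen after their values were seen, and no test was run on them. Cluster 36 was found at P0 alone, with 554 cells, and stayed unnamed because a neutrophil marker, Ltf, is among the genes that lead it, beside Clca3b and Duoxa2, a maturation factor of a hydrogen-peroxide-producing oxidase. It held the suprabasal keratins Krt4 (5321 CPM) and Krt13 (7732 CPM), little of the basal Krt5 (99.0 CPM) and Trp63 (23.96 CPM), little Mki67 (9.77 CPM), the oxidase Duox2 (229.5 CPM) and Lgr5 at 2.90 CPM.

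Cluster 41 of the E16.5 library held 78 cells led by Krt1 and Krt10. It read Krt5 (946 CPM) and Krt14 (1089.5 CPM) but little Krt4 (35.4 CPM), Krt13 (57.9 CPM) and Sox2 (1.07 CPM), and 3.92% of its sexed cells were female. It also held Sprr1b at 371 CPM, while the epithelial-like cluster 28 held 224 CPM at E16.5.

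Ciliated-like cells made up 150 cells at E16.5 and 73 at P0 and none at E13.5. Both male and female signals were read in 22% of them at E16.5 and 19.2% at P0, against 7.05% and 6.72% of all kept cells. Droplets with more than 1 cell may thus add to their levels. The ciliated-like cells read the ciliogenesis factor Foxj1 (371 and 332 CPM) with Krt8 (1494 and 1599.9 CPM), Sox2 (246 and 222 CPM) and Lgr5 at 7.66 and 14.8 CPM. At P0 a lung-epithelial-like cluster of 53 cells held Nkx2-1 (203 CPM), and 4.76% of its sexed cells were female. The 25 gastric-epithelial-like cells at P0 were all female, and 15 of them held a Lgr5 UMI.

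Epithelial transcripts were read in other classes at P0. Krt13 was at 4.09% of its epithelial level in fibroblast-like cells, Krt4 at 3.67% in smooth-muscle-like and 5.86% in blood-endothelial-like cells, and Psca at 10.3% in blood-endothelial-like cells. The suprabasal list had medians of 3.01, 3.20, 3.76, 3.02 and 2.34 (P0 over E16.5) in fibroblast-like, smooth-muscle-like, skeletal-muscle-like, blood-endothelial-like and glia-like cells, against 0.23 in the epithelium. Genes of the epithelium are therefore not read as expressed by those classes.

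In fibroblast-like cells, cluster 8 held Rspo2 at 131 CPM at E16.5, where the class as a whole held 21.4 CPM.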
